A study of Lemna aequinoctialis with 6 samples.

How the data were processed

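RNA of Lemna aequinoctialis was sequenced in 3 control samples and 3 samples treated with indole-3-propionic acid (IPA). Per the labels' protocols, RNA was taken from ground lyophilised plants with a plant RNA kit, libraries were made with a stranded mRNA kit that selects poly(A) RNA, and 150-bp paired ends were read on an Illumina instrument. Groups and replicate numbers were taken from the sample titles. Dose, duration and whether samples were separate cultures were not given in the sources used here.

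The authors deposited a table of 81787 transcripts of 28620 Trinity genes (Trinity is an assembler of transcripts from reads), and the unit of its 6 library columns is a normalised read count, treated here as a signal scaled per library. Per the submitters' processing notes the tools included FastQC, Trimmomatic, BWA, featureCounts and edgeR, and their versions, roles and settings were not given in the sources used here. Every library's values were whole multiples of what 1 read was worth (100% within 0.01 reads, largest deviation 0.00130 reads), so whole reads were recovered. The recovered totals were 38556985, 38877870 and 41370062 reads in control 1, 2 and 3 and 30149649, 45233584 and 36366004 in IPA 1, 2 and 3, and scaling factors implied by the deposited values lay within 1.30% of TMM factors recomputed from the reads. A deposited list by the authors held 5093 transcripts with, per the file headers, a log2 fold change, an average log2 CPM, a likelihood-ratio score, a p-value and an FDR, and its largest FDR was 0.0500 and its smallest absolute log2 fold change 1.00. Its own library values gave the same reads in 30558 of 30558 cases. Gene descriptions, with UniProt names, came from this list alone and covered 6.47% of the transcripts tested. Columns of other samples numbered 0. No genome was used, and positions were not analysed here.

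The design fixed before the data were examined assumed raw counts and edgeR's quasi-likelihood test, but the deposited unit was a normalised signal, so limma (3.58.1) was the main test. Transcripts were kept by filterByExpr of edgeR (4.0.16) on the recovered reads, with a minimum count of 10 (CPM of 0.258 in 3 libraries) and a minimum total of 15, which kept 78722 transcripts of 27147 Trinity genes and left out 3065. Values were tested as log2(value + 0.5) with limma's moderated test with trend and robust estimation in R 4.3.3, IPA against control, and Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate those of low transcripts. As a count test on the recovered reads, edgeR's quasi-likelihood test called 6393 transcripts. On simulated data with 200 of 78722 transcripts changed, the limma step recovered 0, 7, 41 and 50 of 50 at 1.5, 2, 4 and 8-fold, with 26 false among 124 calls. With 6000 changed it recovered 10.7, 51.4 and 98% of 2000 each at 1.5, 2 and 4-fold, with 5.85% of calls false. Changes were planted only in transcripts with an expected mean above 50 reads, so recovery of lower transcripts was not measured. Noise was drawn for each transcript on its own, without a spread between replicates shared across transcripts.

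The rule for named genes, fixed before the data were examined, took the 10 largest rises and the 10 largest falls among transcripts past the threshold with an average log2 CPM of at least 2, groups that did not overlap and an informative description. It also took up to 4 members with the lowest FDR of each gene list past its threshold and of the auxin, photosystem, starch, flavonoid, phenylpropanoid and cell cycle lists. Any gene named outside it was chosen after its values were seen. The 31 gene lists were also fixed beforehand and matched on descriptions: auxin, tryptophan and indole, photosystems, Calvin cycle, chlorophyll, starch, sugar, phenylpropanoid, flavonoid, terpenoid, lipid, nitrogen, mineral transport, cell cycle, histones, cell wall, cytosolic and organellar ribosomal proteins, heat shock, oxidative stress, cytochromes P450, ethylene, jasmonate, abscisic acid, cytokinin, gibberellin and brassinosteroid, defence, root, flowering, organelle and transposon, and cell death. Histones matched 0 described transcripts. The organellar ribosomal list also matched 0, because its wording missed the names used in the descriptions, and organellar members were counted in the cytosolic ribosomal list instead. In all, 29 lists with at least 5 genes counted as rising or falling were tested. This number depends on the calls, so fewer lists could be tested in some alternatives.

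Because descriptions covered only transcripts that the authors had called, no background of unchanged genes existed for these lists, and the planned competitive gene set test (camera), its form with an estimated correlation and the self-contained test (fry) were not run. Instead the numbers of rising and falling genes of a list were compared with those of the other described genes that passed, list members left out, by a two-sided Fisher's exact test (SciPy 1.17.1), which treats genes as independent, with Benjamini-Hochberg adjustment over 29 lists. Of all described genes 1742 passed, of which 962 rose, 774 fell and 6 went both ways. A gene is a Trinity gene, counted as rising or falling where its described transcripts past the threshold went one way, and the values printed for it are those of its transcript of lowest FDR, or of largest change among the largest rises and falls. Of 1000 random lists of 30 genes, 2.20% came under 0.05. Shares of reads have 95% Wilson intervals, which cover counting error only, and group differences in shares were tested by two-sided exact permutation. Groups whose share of reads is given were formed after the data were seen. Those of described transcripts came from the authors' list of changed transcripts alone.

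Replicates were compared by chi-square of their reads over transcripts; the statistic per degree of freedom was 6.52 to 88.5, so no pair agreed within sampling noise. Alternatives were other scalings (RLE, upper quartile, library totals, the 20 most abundant transcripts left out), DESeq2 (1.42.0) and edgeR's exact test on the recovered reads, no filter and a stricter filter, an FDR of 0.01, the replicate number as a block, and each library left out in turn. The quasi-likelihood test of edgeR, planned as the main test, was kept as a further alternative once limma had replaced it. Added after seeing the data were edgeR's likelihood-ratio test, pseudocounts of 0.1 and 1, sums per Trinity gene, lists with isoforms not collapsed or with 1 entry per UniProt name, and lists on the authors' own calls. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.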

Results

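Transcripts of Lemna aequinoctialis, a duckweed (a small floating aquatic plant), were measured by RNA sequencing in 6 samples. The control group and the group treated with IPA (indole-3-propionic acid, an indole compound related in structure to the auxin indole-3-acetic acid) held 3 samples each. The comparison asks which transcripts differed between IPA-treated and control plants, in a study concerned with growth and metabolite yield. The libraries held 38556985, 38877870 and 41370062 reads for control 1, 2 and 3 and 30149649, 45233584 and 36366004 reads for IPA 1, 2 and 3. One read was worth 0.0205 to 0.0318 normalised reads, so that a floor of 3 reads lay between 0.0614 and 0.0954. Features were assembled transcripts with Trinity names, and genome positions were not used here. Levels are given as normalised read count, mean ± SD with n = 3 per group. Fold changes are log2 of IPA over control ± SE on the log2(value + 0.5) scale, which understates the change of low transcripts, and adjusted p-values (FDR) come from limma with Benjamini-Hochberg adjustment. The labels did not say whether the samples of a group were separate cultures, so p-values measure the spread between these samples, which may be technical.

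The 6 libraries separated by treatment on the first principal component, which held 56.5% of the variance. Control 1, 2 and 3 scored -129, -64.2 and -28.3 on it, and IPA 1, 2 and 3 scored 60.1, 74.99 and 86.6. Pearson correlations across transcripts of log2 values were 0.936 to 0.974 within control, 0.968 to 0.988 within IPA and 0.900 to 0.961 between groups. Transcripts are not independent replicates, and the ranges overlapped: control 3 correlated more closely with IPA 1 (0.961) than with control 1 (0.936). Of the 78722 transcripts tested, 25875 (32.9%) had groups that did not overlap, against 10% by chance with 3 against 3. The 20 most abundant transcripts took 29.3, 35.1 and 15.8% of reads in control 1, 2 and 3 and 8.08, 9.96 and 7.62% in IPA 1, 2 and 3. The group means were 26.7 ± 9.87% and 8.55 ± 1.24% (two-sided exact permutation p = 0.1, the smallest possible with 3 against 3).

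**Figure D1:**
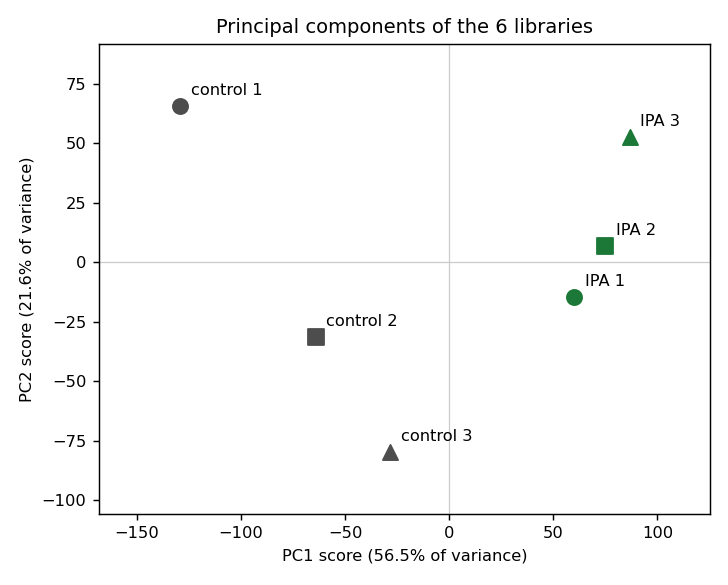
Scores of the 6 libraries on the first (x axis, 56.5% of variance) and second (y axis, 21.6% of variance) principal components of log2 normalised read counts, control in grey and IPA in green, with circle, square and triangle for replicates 1, 2 and 3. The control libraries lie between -129 and -28.3 on the x axis and the IPA libraries between 60.1 and 86.6.

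Among described transcripts with an average log2 CPM of at least 2, the 10 with the largest rises in IPA were led by ORR6, a response regulator of the cytokinin pathway, and a pectinesterase, and included 4 light-harvesting proteins. The 10 with the largest falls were led by a pair of polygalacturonases, metacaspase-6 and the auxin response transcript SAUR50. In all, 6587 of 78722 transcripts (8.37%) passed limma's FDR of 0.05, of which 3538 rose and 3049 fell. Among them 3776 changed at least 2-fold, 2059 up and 1717 down. At an unadjusted limma p under 0.05 there were 20892 transcripts. With library totals in place of the deposited scaling, which moved the median transcript by 0.25 log2, 84.1% of the calls rose against 53.7% here, and among those of at least 2-fold 81.4% against 54.5%. Single libraries moved the count of all calls: it was 1519 without control 2, 10421 without control 3, 3570 without IPA 1, 1293 without IPA 2 and 2502 without IPA 3, and the count of at least 2-fold was 1512 without control 2, 5941 without control 3, 1293 without IPA 2 and 2321 without IPA 3.

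Among the 10 largest named rises, the response regulator ORR6, a negative regulator type of cytokinin signalling that is itself induced by cytokinin, went from 19.3 ± 7.39 to 404 ± 68.8 (log2 4.40 ± 0.26, limma FDR 0.000166). Probable pectinesterase 8, of a family that demethylesterifies cell wall pectin, rose from 0.239 ± 0.0147 to 13.2 ± 9.60 (log2 3.997 ± 0.40, FDR 0.00102). Probable alkaline/neutral invertase F, which cleaves sucrose, rose from 1.73 ± 0.427 to 20.6 ± 6.97 (log2 3.20 ± 0.26, FDR 0.000324). ACT domain-containing protein ACR6 rose from 2.36 ± 0.841 to 26.1 ± 3.19 (log2 3.25 ± 0.23, FDR 0.000212). Purple acid phosphatase 2, of a family tied to phosphate recovery, rose from 0.372 ± 0.180 to 9.15 ± 5.00 as a single transcript (log2 3.36 ± 0.34, FDR 0.000877), and the sum over its isoforms did not pass (log2 0.30, limma FDR 0.447). Another gene with the same description fell from 8.73 ± 1.40 to 3.98 ± 0.179 (log2 -1.03 ± 0.19, limma FDR 0.0107). Transcription factor BHLH6 rose from 0.528 ± 0.383 to 12.1 ± 11.5 (log2 3.28 ± 0.63, FDR 0.0209), a call lost without control 1 (limma FDR 0.112), control 2 (0.0638) or IPA 2 (0.0502). The remaining 4 were chlorophyll a-b binding proteins with log2 changes of 3.17 to 3.58.

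The 10 largest named falls began with a pair of polygalacturonases, enzymes that cut pectin, which fell from 38.6 ± 38.0 to 0.200 ± 0.193 (log2 -5.15 ± 0.83, limma FDR 0.0128) and from 20.2 ± 19.0 to 0.219 ± 0.252 (log2 -4.36 ± 0.73, FDR 0.0145). Metacaspase-6, a cysteine protease of a family linked to programmed cell death, fell from 31.4 ± 18.3 to 1.16 ± 0.350 (log2 -4.12 ± 0.38, FDR 0.000877). The early auxin response transcript SAUR50 stood at 9.81 ± 5.12 in control and at 0, 0.0409 and 0.0989 in IPA 1, 2 and 3 (log2 -4.11 ± 0.34, FDR 0.000362), values near the floor whose fold depends on the pseudocount. Protease inhibitor HPI fell from 94.6 ± 56.0 to 4.88 ± 1.72 (log2 -4.01 ± 0.45, FDR 0.00223) and Glu S.griseus protease inhibitor from 27.0 ± 17.9 to 1.02 ± 0.461 (log2 -4.004 ± 0.46, FDR 0.00247). The pathogenesis-related protein of PR-1 type fell from 150 ± 43.2 to 11.8 ± 1.83 (log2 -3.58 ± 0.24, FDR 0.000166). Chaperone protein DnaJ (log2 -3.74 ± 0.38), Pectinesterase inhibitor 10 (log2 -3.54 ± 0.33) and Elicitor-responsive protein 1 (log2 -3.38 ± 0.63) completed the set, with limma FDR of 0.00113, 0.000652 and 0.0197. The call on Elicitor-responsive protein 1 was lost without control 2 (limma FDR 0.0571), IPA 2 (0.0526) or IPA 3 (0.0661). Control 1 held the highest control value in 69.5% of the transcripts that fell, and IPA 3 the highest IPA value in 55.4% of those that rose. Near-identical members of these families, polygalacturonases and chlorophyll a-b binding proteins among them, may share reads, so that which copy changed is uncertain.

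**Figure D2:**
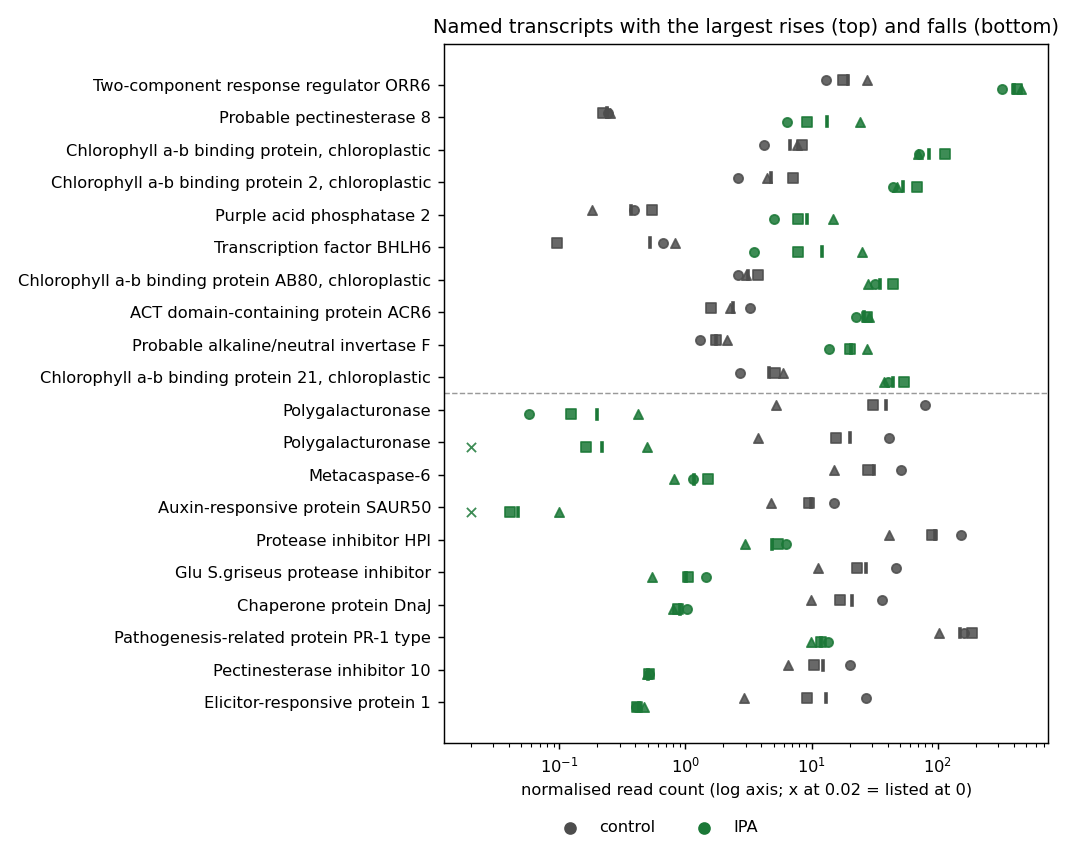
Normalised read count (x axis, log scale) of the 10 named transcripts with the largest rises (top) and the 10 with the largest falls (bottom), control in grey and IPA in green, with circle, square and triangle for replicates 1, 2 and 3, short vertical bars for the means and a cross at 0.02 for a library listed at 0. ORR6 lies at 404 ± 68.8 in IPA against 19.3 ± 7.39 in control, and SAUR50 is listed at 0 in IPA 1.

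Genes of the photosystems and their antennae rose together in IPA. Chlorophyll a-b binding protein AB80, an antenna protein of photosystem II, rose from 3.13 ± 0.605 to 34.7 ± 8.31 (log2 3.27 ± 0.22, limma FDR 0.000166), and a further chlorophyll a-b binding protein from 6.74 ± 2.24 to 84.9 ± 24.9 (log2 3.58 ± 0.28, FDR 0.000324). The antenna proteins LHCII type III and CP24 10A rose from 27.5 ± 4.13 to 187 ± 34.9 (log2 2.74 ± 0.20, FDR 0.000244) and from 21.4 ± 3.29 to 124 ± 17.2 (log2 2.50 ± 0.19, FDR 0.000249). Of 33 described genes of the list, 30 rose, 2 fell and 1 did not pass. Both that fell, named after their values were seen, belong to the reaction centres and are plastid-encoded: apoprotein A2 of photosystem I fell from 5267 ± 1766 to 789 ± 171 (log2 -2.71 ± 0.27, limma FDR 0.000730) and the CP47 protein of photosystem II from 60.7 ± 31.5 to 15.9 ± 3.49 (log2 -1.79 ± 0.35, FDR 0.0180). Photosystem II protein D1, also plastid-encoded, was at 88.4 ± 59.6 and 26.1 ± 5.58 (limma FDR 0.161). The split differed from that of the other described genes that passed (two-sided Fisher's exact test, adjusted p = 6.64e-05; 55.4% rose over all described genes that passed, the list's own included), and it stayed past the threshold in 23 of 23 alternatives (highest adjusted p = 0.00378). Of 72 described transcripts 70 passed over all transcripts tested and 72 adjusted over the list alone. Descriptions exist here only for transcripts that the authors listed as changed on these samples, so neither count is independent evidence, here or for the lists that follow. The share of reads from transcripts with ribosomal RNA descriptions moved the other way, from 21.4 ± 8.83% in control to 5.79 ± 1.06% in IPA.

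Genes of carbon fixation rose as well. The RuBisCO small subunit 6 rose from 155 ± 26.5 to 409 ± 85.3 (log2 1.39 ± 0.21, limma FDR 0.00495) in one gene and from 19.7 ± 6.82 to 53.2 ± 8.78 (log2 1.45 ± 0.25, FDR 0.00845) in another, the latter call lost without IPA 2 (limma FDR 0.0562). The alpha subunit of the RuBisCO large subunit-binding protein, a chaperonin, rose from 68.3 ± 19.6 to 154 ± 17.5 (log2 1.20 ± 0.23, FDR 0.0138), and chloroplastic fructose-1,6-bisphosphatase from 7.95 ± 1.38 to 17.5 ± 4.05 (log2 1.08 ± 0.22, FDR 0.0165). The chaperonin call was lost without control 2 (limma FDR 0.0630), IPA 2 (0.0723) or IPA 3 (0.0568), and that on the bisphosphatase without control 2 (0.0754), IPA 2 (0.0838) or IPA 3 (0.0624). Of 9 described Calvin cycle genes, chosen by the authors on these samples, 8 rose and none fell (Fisher's exact test, adjusted p = 0.0427). The member that did not pass was the large chain of RuBisCO, plastid-encoded, at 12.2 ± 9.35 and 3.81 ± 1.28 (limma FDR 0.200). Of 17 described transcripts 16 passed over all transcripts tested and 16 adjusted over the list alone. The list stayed past the threshold in 4 of 20 alternatives (adjusted p up to 0.184). It lost its call without control 1 (Fisher's exact adjusted p = 0.0658), control 3 (0.0520) or IPA 1 (0.184). Without control 2, IPA 2 or IPA 3 fewer than 5 of its genes counted as rising or falling, so it was not tested. With calls from edgeR's quasi-likelihood test (0.0816), DESeq2 (0.0905), the exact (0.0871) or the likelihood-ratio test (0.0946), Fisher's exact adjusted p also missed the threshold.

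Among starch genes, Beta-amylase Tri a 17, an enzyme of starch breakdown, rose from 1.40 ± 0.227 to 11.5 ± 5.29 (log2 2.57 ± 0.30, limma FDR 0.00131) and, in another gene, from 0.710 ± 0.522 to 5.08 ± 1.88 (log2 2.24 ± 0.34, FDR 0.00507). The 1,4-alpha-glucan-branching enzyme 1, which branches growing starch, rose from 73.7 ± 11.8 to 192 ± 46.5 (log2 1.36 ± 0.21, FDR 0.00547). Probable alpha-amylase 2 rose from 0.203 ± 0.0805 to 1.22 ± 0.484 (log2 1.27 ± 0.23, FDR 0.0119), a call lost without control 2 (limma FDR 0.0562). Of 10 described starch genes 7 rose and none fell, yet the list's split missed the threshold (Fisher's exact test, adjusted p = 0.0561). Of 27 described transcripts 15 passed over all transcripts tested and 25 adjusted over the list alone, all from the authors' selection on these samples. The chlorophyll and tetrapyrrole list missed it too (6 rose, none fell of 9 described, adjusted p = 0.0706, with 13 of 17 transcripts over all tested and 17 adjusted over the list alone). Its Protochlorophyllide reductase B, an enzyme of the light-dependent step of chlorophyll synthesis named after its values were seen, rose from 42.1 ± 11.1 to 137 ± 14.5 (log2 1.73 ± 0.22, limma FDR 0.00178). Across alternatives the adjusted p ranged from 0.000240 to 0.178 for starch, past the threshold in 9 of 21, among them without control 3 (0.0255), and from 0.000780 to 0.479 for chlorophyll, past it in 1 of 20.

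Auxin genes went both ways. IAA7, a transcriptional repressor of auxin signalling, rose from 5.34 ± 1.07 to 24.5 ± 4.95 (log2 2.10 ± 0.21, limma FDR 0.000796). The auxin response factors 19 and 16 rose from 0.566 ± 0.203 to 2.86 ± 0.640 (log2 1.65 ± 0.23, FDR 0.00314) and from 0.560 ± 0.210 to 2.54 ± 0.647 (log2 1.52 ± 0.24, FDR 0.00536), while SAUR50 fell, as given above. Of 34 described genes that the authors had selected on these samples 20 rose, 8 fell, 1 had transcripts going both ways and 5 did not pass, and the split did not differ from that of other described genes (Fisher's exact test, adjusted p = 0.199; none of 23 alternatives passed, lowest adjusted p = 0.0582). Of 47 described transcripts 36 passed over all transcripts tested and 47 adjusted over the list alone. In the tryptophan and indole list, 1 of 9 described genes rose and 7 fell (adjusted p = 0.0671; 20 of 23 transcripts over all tested and 23 adjusted over the list alone), and the list passed in 3 of 22 alternatives (0.000121 to 0.348), among them without IPA 1 (Fisher's exact adjusted p = 0.0391). Named after their values were seen, Anthranilate phosphoribosyltransferase, an early enzyme of tryptophan synthesis, fell from 390 ± 92.5 to 78.5 ± 3.87 (log2 -2.28 ± 0.20, limma FDR 0.000389), and Tryptophan decarboxylase 1 fell from 137 ± 41.5 to 34.7 ± 11.7 (log2 -1.99 ± 0.31, FDR 0.00618). YUCCA1, an enzyme that makes indole-3-acetic acid and the list's sole riser, rose from 1.91 ± 0.532 to 6.38 ± 0.796 (log2 1.53 ± 0.22, FDR 0.00369).

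Cytokinin genes rose in 11 of 14 described cases and fell in 1, and the list missed the threshold (Fisher's exact test, adjusted p = 0.0561). Across alternatives its adjusted p ranged from 1.66e-08 to 0.175, past the threshold in 11 of 23. Among these were the fits without control 3 (0.0376), IPA 1 (0.0374) or IPA 2 (0.0467). It also passed with calls from edgeR's quasi-likelihood test (Fisher's exact adjusted p = 0.0377), DESeq2 (0.0451), the exact test (0.0485) or the likelihood-ratio test (0.0494). Whether this list passed thus depended on the test that called the genes. Beside ORR6, and named after its values were seen, Cytokinin dehydrogenase 3, which degrades cytokinins, rose from 3.37 ± 0.746 to 27.1 ± 4.83 (log2 2.84 ± 0.21, limma FDR 0.000260). The member that fell, PRR95, is a clock-type pseudo-response regulator (log2 -1.13 ± 0.22, limma FDR 0.0158). Of 52 described transcripts, a selection of the authors on these samples, 40 passed over all transcripts tested and 50 adjusted over the list alone.

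Ethylene genes named by the rule included transcription factors of the ERF family. ERF036 rose from 7.19 ± 0.251 to 26.2 ± 7.83 (log2 1.76 ± 0.22, limma FDR 0.00198), ERF053 from 0.156 ± 0.0869 to 1.37 ± 0.224 (log2 1.51 ± 0.20, FDR 0.00255) and ERF098 from 4.48 ± 1.34 to 20.8 ± 7.40 (log2 2.07 ± 0.28, FDR 0.00272). Ethylene-overproduction protein 1, of a family that limits ethylene synthesis, rose from 1.40 ± 0.373 to 4.93 ± 0.0810 (log2 1.54 ± 0.21, FDR 0.00264). Of 39 described genes, again taken from the authors' selection on these samples, 21 rose and 5 fell (Fisher's exact test, adjusted p = 0.0427), with 54 of 79 transcripts passing over all transcripts tested and 76 adjusted over the list alone. The list stayed past the threshold in 13 of 23 alternatives (adjusted p up to 0.282), and lost its call without control 1 (Fisher's exact adjusted p = 0.158), control 2 (0.105), IPA 2 (0.233) or IPA 3 (0.282).

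Genes of phenylpropanoid and lignin synthesis fell in most cases. Dirigent protein 21, of a family that steers the coupling of phenolic radicals, fell from 113 ± 35.2 to 23.0 ± 2.54 (log2 -2.22 ± 0.24, limma FDR 0.000952). Dirigent protein 17 fell from 37.9 ± 8.68 to 13.8 ± 1.29 as a single transcript (log2 -1.40 ± 0.21, FDR 0.00407), while the sum over its isoforms did not pass (log2 -0.06, limma FDR 0.910). Tryptamine hydroxycinnamoyltransferase 1, which joins phenolic acids to amines, fell from 52.6 ± 14.4 to 12.1 ± 4.79 (log2 -2.11 ± 0.31, FDR 0.00506). Against them the cinnamoyl-CoA reductase-like SNL6 rose from 3.44 ± 0.185 to 18.4 ± 6.01 (log2 2.21 ± 0.24, FDR 0.000996). Phenylalanine ammonia-lyase, the entry enzyme of the pathway, named after its values were seen, fell from 92.5 ± 30.8 to 25.8 ± 9.63 (log2 -1.84 ± 0.33, FDR 0.0133). Of 30 described genes, which the authors had chosen on these samples, 3 rose and 19 fell (Fisher's exact test, adjusted p = 0.00141), with 43 of 62 transcripts passing over all transcripts tested and 62 adjusted over the list alone. The list lost its call without control 1 (adjusted p = 0.0515) or control 2 (Fisher's exact adjusted p = 0.105, the highest of 23 alternatives, the lowest being 3.78e-07).

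Flavonoid genes showed no common direction. Flavonoid 3'-monooxygenase CYP75B137, which hydroxylates the flavonoid B ring, rose from 0.174 ± 0.0870 to 3.01 ± 1.21 (log2 2.33 ± 0.27, limma FDR 0.00121), and the glucosyltransferase UGT89B1 from 3.42 ± 0.306 to 8.91 ± 1.67 (log2 1.25 ± 0.19, FDR 0.00530). Flavanone 3-dioxygenase 2 rose from 6.24 ± 1.96 to 28.5 ± 15.8 (log2 2.01 ± 0.37, FDR 0.0148), a call lost without control 2 (limma FDR 0.0578) or IPA 2 (0.0552). Dihydroflavonol 4-reductase, of the anthocyanin branch, fell from 1.55 ± 0.428 to 0.0851 ± 0.102 as a single transcript (log2 -1.80 ± 0.23, FDR 0.00202), and summed over its isoforms it did not pass (log2 -0.81, limma FDR 0.0794). Of 9 described genes from the authors' selection on these samples 5 rose, 3 fell and 1 went both ways (Fisher's exact test, adjusted p = 0.815; 0.571 to 1 over 23 alternatives), with 26 of 29 transcripts passing over all transcripts tested and 29 adjusted over the list alone.

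Peroxidases led the falls among genes of oxidative stress and detoxification. Peroxidase 72 fell from 7.25 ± 2.28 to 0.343 ± 0.225 (log2 -3.19 ± 0.26, limma FDR 0.000324). In 3 genes described as Peroxidase 5, near-identical copies of which may share reads, levels fell from 15.8 ± 4.37 to 1.61 ± 0.147 (log2 -2.92 ± 0.23, FDR 0.000324), from 64.5 ± 19.7 to 7.95 ± 1.55 (log2 -2.91 ± 0.25, FDR 0.000389) and from 9.99 ± 2.73 to 0.968 ± 0.382 (log2 -2.84 ± 0.27, FDR 0.000564). These belong to the secreted class III peroxidases, which act in the cell wall. Of 55 described genes 12 rose and 31 fell (Fisher's exact test, adjusted p = 0.00267), with 83 of 112 transcripts passing over all transcripts tested and 109 adjusted over the list alone, and the authors had chosen these members on the same samples. With 1 entry per UniProt name the list missed the threshold (adjusted p = 0.0524, the highest of 23 alternatives, the lowest being 1.24e-05).

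Defence genes fell more often than they rose. Beside the PR-1 type protein, Acidic endochitinase, of a family that degrades fungal chitin, fell from 19.2 ± 4.67 to 1.45 ± 0.279 (log2 -3.32 ± 0.22, limma FDR 0.000166). Germin-like protein 8-2 fell from 7.64 ± 1.38 to 0.890 ± 0.429 (log2 -2.59 ± 0.26, FDR 0.000796), and the transcription factor WRKY28 from 251 ± 41.8 to 55.8 ± 17.9 (log2 -2.20 ± 0.24, FDR 0.00103). Of 58 described genes 16 rose, 32 fell and 1 went both ways (Fisher's exact test, adjusted p = 0.0206), with 117 of 134 transcripts passing over all transcripts tested and 130 adjusted over the list alone. These members too were picked by the authors on these samples. The call was lost without IPA 2 (adjusted p = 0.0501) and with 1 entry per UniProt name (Fisher's exact adjusted p = 0.0524, the highest of 23 alternatives, the lowest being 1.24e-05). The falls in these lists went with a top-20 share of reads of 26.7 ± 9.87% in control against 8.55 ± 1.24% in IPA.

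Among described transcripts of organelles and mobile elements, 3 genes rose and 12 fell, a direction that library totals (10 rose, 10 fell) or leaving out IPA 1 (3 rose, 2 fell) did not keep. The reading frame ycf68, which lies in the ribosomal RNA operon of plastids, fell from 19553 ± 6748 to 5732 ± 867 (log2 -1.71 ± 0.29, limma FDR 0.00839). A polyprotein of Ty3-G type, from a retrotransposon, fell from 21.0 ± 8.13 to 6.67 ± 0.198 (log2 -1.50 ± 0.28, FDR 0.0117), while one of RE2 type rose from 2.35 ± 0.285 to 7.01 ± 1.40 (log2 1.38 ± 0.21, FDR 0.00426). Nuclear intron maturase 2, a nuclear gene for a mitochondrial splicing protein, rose from 0.483 ± 0.102 to 2.22 ± 0.680 (log2 1.45 ± 0.23, FDR 0.00578). Without control 2 the calls on ycf68 (limma FDR 0.0637) and Ty3-G (0.0716) were lost, the latter also without IPA 2 (0.0616). Of 38 described genes, selected by the authors on these samples, 3 rose and 12 fell (Fisher's exact test, adjusted p = 0.0427), with 18 of 46 transcripts passing over all transcripts tested and 46 adjusted over the list alone. The list stayed past the threshold in 9 of 21 alternatives (adjusted p up to 1), and lost its call without control 1 (Fisher's exact adjusted p = 0.0515), IPA 1 (1) or IPA 3 (0.265). Without control 2 or IPA 2 fewer than 5 of its genes counted as rising or falling, so it was not tested.

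The share of reads behind such transcripts was then measured in groups formed after the data were seen. Transcripts whose descriptions name reading frames within ribosomal RNA took 24.0, 28.7 and 11.6% of reads in control 1, 2 and 3 and 5.46, 6.98 and 4.94% in IPA 1, 2 and 3, and of 6 such genes 5 fell and none rose. The widest 95% Wilson interval was 0.014 percentage points either side, which covers counting error only. Plastid-encoded transcripts took 0.508 ± 0.115% and 0.104 ± 0.0170% of reads (6 of 16 genes fell, none rose). Most reads of this plastid group came from 1 transcript, apoprotein A2 of photosystem I. It held 4981 of 5555, 7159 of 7865 and 3662 of 3898 normalised reads in control 1, 2 and 3. In IPA 1, 2 and 3 it held 741 of 853, 978 of 1136 and 647 of 807. The plastid group left out ycf68, which was counted in the ribosomal group although it lies in the plastid operon. That transcript held 22879, 23992 and 11787 normalised reads in control 1, 2 and 3, more than the plastid group. In IPA 1, 2 and 3 it held 4751, 6047 and 6397. Mitochondria-encoded transcripts took 0.267 ± 0.208% and 0.0454 ± 0.0101% (2 of 19 fell, none rose). Cytochrome b, among those that fell, was an isoform of the same Trinity gene as ycf68, so the groups were not fully separate. Nuclear genes of the photosystems and antennae took 0.218 ± 0.0546% and 0.951 ± 0.111% (30 of 30 rose). Two-sided exact permutation tests of the shares gave p = 0.1 for the ribosomal, plastid and nuclear photosystem groups, the smallest possible with 3 against 3, and p = 0.2 for the mitochondrial group, where control 3 was at 0.0471%. All members were transcripts that the authors had listed as changed between these same samples. Separation of the shares was thus partly built in, and these p-values are not independent evidence.

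**Figure D3:**
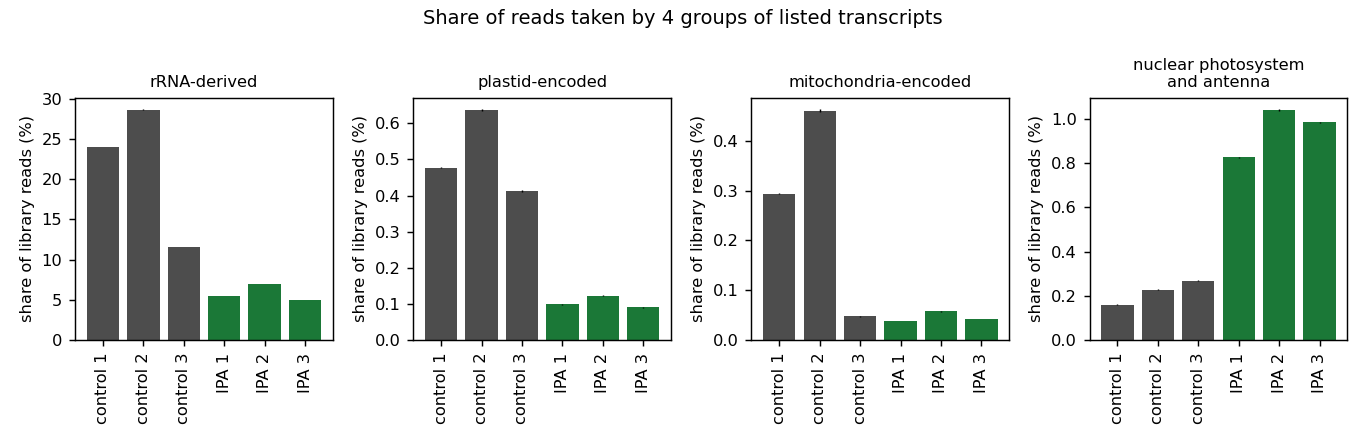
Share of library reads in percent (y axes, each panel with its own scale from 0) taken by 4 groups of described transcripts in each of the 6 libraries (x axis), control in grey and IPA in green, with 95% Wilson intervals as error bars. The ribosomal group takes 24.0, 28.7 and 11.6% in the control libraries and 4.94 to 6.98% in the IPA libraries, and the nuclear photosystem group 0.218 ± 0.0546% and 0.951 ± 0.111%.

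Cell cycle genes did not share a direction. Cyclin-D1-1, which drives entry into the cell cycle, rose from 3.29 ± 0.256 to 8.53 ± 1.44 (log2 1.24 ± 0.19, limma FDR 0.00493), and the replication licensing protein CDC6 homolog B from 1.17 ± 0.447 to 4.88 ± 1.69 (log2 1.68 ± 0.28, FDR 0.00731), a call lost without control 2 (limma FDR 0.0514). Cyclin-dependent kinase inhibitor 5, which restrains the cycle, rose from 3.72 ± 0.702 to 8.32 ± 1.10 (log2 1.07 ± 0.20, FDR 0.0131), and was lost without control 2 (limma FDR 0.0676) or IPA 2 (0.0863). A homolog of RNA-directed DNA polymerase, an enzyme of mobile elements that the list's wording also took in, fell from 8.92 ± 3.34 to 3.16 ± 0.118 (log2 -1.30 ± 0.26, FDR 0.0154), and was lost without control 2 (0.0700), IPA 2 (0.0699) or IPA 3 (limma FDR 0.0562). Of 32 described genes from the authors' selection on these samples 10 rose and 6 fell (Fisher's exact test, adjusted p = 0.785; 0.0172 to 1 over 21 alternatives), with 31 of 75 transcripts passing over all transcripts tested and 70 adjusted over the list alone.

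The remaining lists missed the threshold of Fisher's exact test, and their members were likewise chosen by the authors on these samples. Lipid synthesis had 24 rising and 8 falling genes of 46 (adjusted p = 0.0671), cell wall growth 46 and 21 of 77 (0.0672), and heat shock proteins and chaperones 21 and 6 of 37 (0.0561). Programmed cell death and DNA damage had 2 rising and 8 falling genes of 14 (adjusted p = 0.0671), flowering and pollen 6 and 12 of 24 (0.168), and cytochromes P450 with glycosyltransferases 31 and 15 of 62 (0.172). Sugar transport had 6 rising and 4 falling genes of 14 (adjusted p = 1), terpenoids 8 and 3 of 13 (0.502), nitrogen assimilation 4 and 2 of 12 (0.810), mineral transport 7 and 3 of 15 (0.694) and cytosolic ribosomal proteins, some of them organellar, 4 and 2 of 19 (0.810). Jasmonate genes rose in 7 and fell in 5 of 16 cases (adjusted p = 1), abscisic acid genes in 5 and 1 of 9 (0.358), gibberellin and brassinosteroid genes in 6 and 2 of 9 (0.451), and root markers in 5 and 5 of 12 (0.815). Transcripts passing over all transcripts tested, and then adjusted over the list alone, numbered 53 and 74 of 74 for lipid synthesis, 158 and 185 of 186 for cell wall growth, 47 and 63 of 63 for heat shock and 37 and 50 of 50 for cell death. They numbered 41 and 67 of 67 for flowering, 83 and 114 of 115 for cytochromes P450, 30 and 41 of 41 for sugar transport, 22 and 26 of 26 for terpenoids, 13 and 30 of 30 for nitrogen and 24 and 29 of 29 for mineral transport. For the ribosomal list they were 7 and 18 of 21, for jasmonate 34 and 44 of 44, for abscisic acid 26 and 31 of 31, for gibberellin and brassinosteroid 17 and 19 of 19, and for root markers 22 and 26 of 26. Over the 29 lists tested, 1196 of 1614 transcripts passed over all transcripts tested and 1589 adjusted over the list alone. Of these lists, 7 passed, 3 toward rising and 4 toward falling genes. The number was 4 of 29 lists testable without control 1, 4 of 17 without control 2, 4 of 15 without IPA 2, 6 of 23 without IPA 3, 8 of 28 without IPA 1 and 10 of 29 without control 3. Some single libraries brought a list past the threshold when left out: lipid synthesis without control 1 (Fisher's exact adjusted p = 0.0401), control 3 (0.0427) or IPA 3 (0.0458), heat shock without control 3 (0.0211), cell death without control 2 (0.0248) or IPA 1 (0.0256), and flowering without IPA 3 (0.0458). Over their alternatives these adjusted p-values ranged from 0.000154 to 0.184, 0.0211 to 1, 2.42e-07 to 0.188 and 7.88e-05 to 0.318. Cell wall growth passed in 4 of 23 alternatives, upper-quartile factors (0.0460), the stricter filter (0.0458), 1 entry per UniProt name (0.00187) and isoforms not collapsed, with Fisher's exact adjusted p from 1.42e-05 to 1. With isoforms not collapsed, and in no other alternative, sugar transport (0.0244 to 1 over alternatives), mineral transport (0.00689 to 1) and abscisic acid (0.000114 to 0.806) passed as well.

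**Figure D4:**
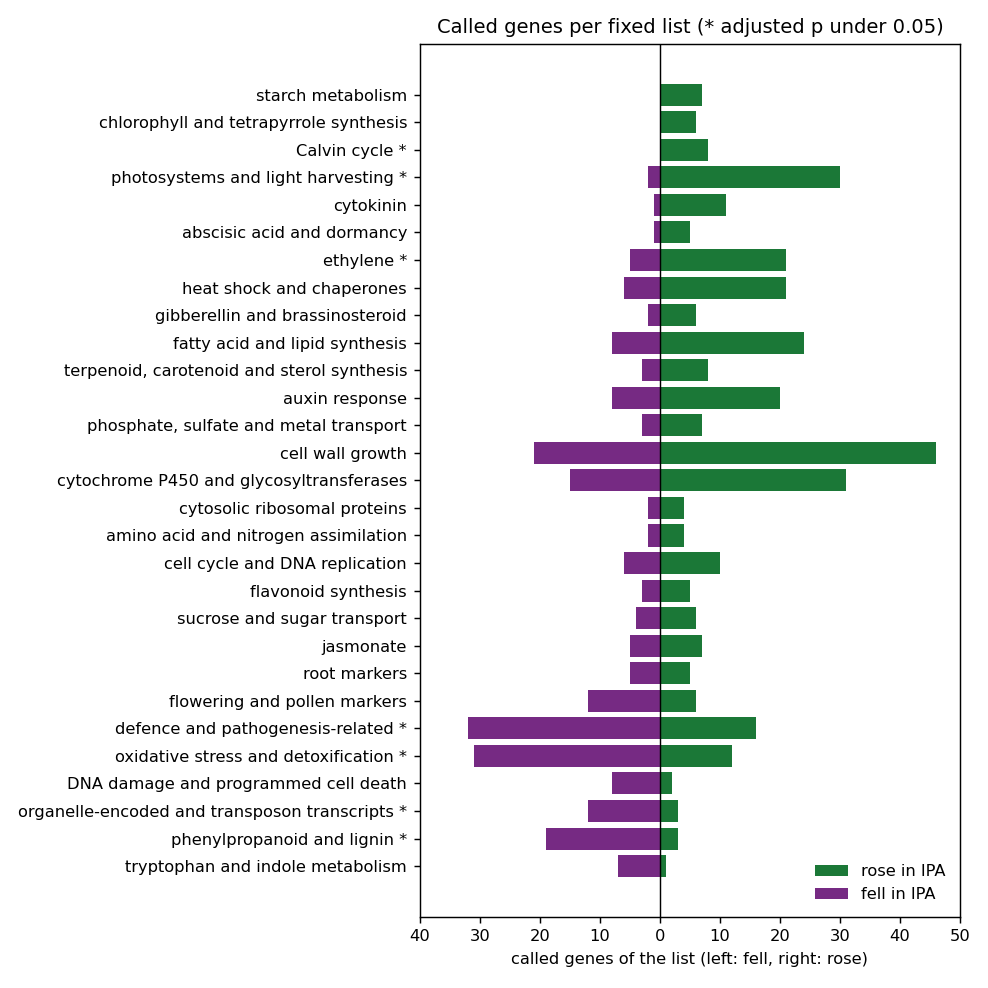
Number of described genes that fell (bars to the left, purple) and rose (bars to the right, green) in IPA for each of the 29 gene lists tested, with an asterisk for an adjusted p under 0.05 in Fisher's exact test. Photosystems and light harvesting had 30 rising against 2 falling genes, and phenylpropanoid and lignin 3 against 19.

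The authors' deposited table of changed transcripts held 5093 transcripts, 2586 higher and 2507 lower in IPA. Of these, 3485 (68.4%) passed limma's FDR of 0.05 here, and the 1608 others did not. The sign was the same in 5093 of 5093, but that table was made from these same libraries and held only changes of at least 2-fold. This agreement is therefore not independent evidence. With edgeR's likelihood-ratio test on the recovered reads 5088 passed, with log2 fold changes within 0.0038 of the authors'. A further 3102 transcripts that passed limma's FDR here, 1061 of them at least 2-fold, were not in that table and carried no description. The likelihood-ratio test passed all 6587 transcripts that limma passed, and gave 7554 of at least 2-fold. Every transcript in the authors' table (100%) carried a description. Absence from that table therefore need not mean that the authors' test missed a transcript. For ORR6 the authors' deposited table gave a log2 fold change of 4.39 against 4.40 here, and for the low transcript SAUR50 -7.58 against -4.11. The overlap fell to 1150 without control 2, 975 without IPA 2 and 1673 without IPA 3.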

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

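The quasi-likelihood test of edgeR, the main test of the design fixed beforehand, became an alternative when limma replaced it. Alternatives added after the data were seen were edgeR's likelihood-ratio test, pseudocounts of 0.1 and 1, sums per Trinity gene, isoforms not collapsed, 1 entry per UniProt name and the authors' own calls. Against 6587 transcripts past the threshold here, library totals gave 11817, DESeq2 10358, edgeR's exact test 10862, the likelihood-ratio test 11216, sums per Trinity gene 2812 (fewer features tested) and an FDR under 0.01 1376 (a stricter threshold). Against 3776 of at least 2-fold these gave 5915, 6844, 7369, 7554 and, per Trinity gene, 1605. Left-out libraries ranged from 1293 (IPA 2) to 10421 (control 3) for all calls and from 1293 to 5941 for those of at least 2-fold. RLE (6460), upper-quartile (6837), quasi-likelihood (6393), no filter (6541), the stricter filter (6438), the 20 most abundant left out (6324) and pseudocounts 0.1 and 1 (6511 and 6413) stayed within 1.5 times. Apart from the stricter threshold and the smaller feature number, the cause was not tested. Left-out libraries also made a group smaller, yet all calls rose to 7233 without control 1 and 10421 without control 3.

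With the replicate number as a block, calls numbered 4377, those of at least 2-fold 3421, and lists past the threshold 4, ending the calls on the Calvin cycle (Fisher's exact adjusted p = 0.0526), ethylene (0.221) and organelle and transposon lists (0.158). Deviations of same-numbered libraries from their group means correlated at -0.087, 0.082 and -0.134 for numbers 1, 2 and 3. Control 2 matched best with IPA 2, but control 1 and control 3 with IPA 3 and IPA 1. These values showed no common link by number, but so few correlations cannot exclude that same-numbered samples were paired.

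Against 7 lists past the threshold, RLE, no filter, the 20 most abundant left out and pseudocount 1 gave 4, upper-quartile factors and pseudocount 0.1 gave 11, isoforms not collapsed gave 19 (more features counted) and left-out libraries 4 to 10, with only 17 lists testable without control 2 and 15 without IPA 2. Library totals and quasi-likelihood gave 7, DESeq2, the exact and likelihood-ratio tests and the authors' own calls 9, the stricter filter 8, and sums per Trinity gene and UniProt names 5. The overlap of 3485 with the authors' list ranged over left-out libraries from 975 (IPA 2) to 4096 (control 3), and was 4667 with DESeq2, 5003 with the exact test and 5088 with the likelihood-ratio test. Non-overlapping transcripts kept within 1.5 times of 25875 under other scalings and filters (21792 to 26606). With a library left out they numbered 29690 to 38275. More transcripts separate by chance in such smaller groups, so these counts are not comparable with 25875. None of the 60 named genes lost its call under another scaling, tool, filter, pseudocount or the block. With the 20 most abundant left out, ycf68 was itself removed and so not tested. All 60 came from the authors' list on these samples and were picked for large changes or low FDR. Kept calls were therefore likely beforehand and are not independent evidence. Calls were lost for 11 genes without control 2, 9 without IPA 2, 4 without IPA 3, 1 without control 1 and 3 when summed per Trinity gene. None reversed. The median log2 fold change of leucine-rich-repeat receptor-like kinases, a group formed after the data were seen, reversed from -0.87 to 0.99 under the stricter filter. A filter leaves each transcript's fold change as it was, so the reversal came from which members were kept.

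At 1.5-fold, simulation gave 10.7% recovery with 6000 transcripts changed and 0 of 50 with 200 changed. Small changes were thus mostly below detection with 3 libraries per group among the better-covered transcripts simulated as changed. Recovery of lower transcripts was not measured. The planned competitive gene set test with preset or estimated correlation and the self-contained test were not run, because descriptions covered only transcripts called by the authors.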

Other observations

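Tests chosen only after the result was seen were those of the gene groups described first, whose example genes were also picked then, both tests on ribosomal and organelle transcripts, and the counts over other splits of the samples. Genes for very-long-chain lipids and wax, which build the surface cuticle, rose in 28 and fell in 5 of 41 described cases (Fisher's exact test, adjusted p = 0.00444 over 16 such groups), and their share of reads went from 0.0515 ± 0.00226% in control to 0.194 ± 0.0376% in IPA (n = 3 each, two-sided exact permutation p = 0.1, the smallest possible). The planned lipid list missed the threshold (Fisher's exact adjusted p = 0.0671). Between control and IPA the share of reads from listed transcripts with ribosomal RNA descriptions moved from 21.4 ± 8.83% to 5.79 ± 1.06%. That of the 20 most abundant transcripts moved from 26.7 ± 9.87% to 8.55 ± 1.24%. The elongation enzyme 3-ketoacyl-CoA synthase 9 rose from 1.71 ± 0.268 to 6.93 ± 1.01 normalised reads (log2 1.75 ± 0.20, limma FDR 0.00110), and Glycerol-3-phosphate 2-O-acyltransferase 4 from 1.45 ± 0.332 to 8.84 ± 2.99 (log2 2.23 ± 0.25, limma FDR 0.00110). The 5 described type-A response regulators, ORR4, ORR6 and ORR10 in name, rose together, with a log2 change of 2.02 to 4.40 as the median over each gene's transcripts (Fisher's exact adjusted p = 0.111), from 0.0136 ± 0.00300% to 0.125 ± 0.0238% of reads. Ferredoxin-nitrite reductase, which reduces nitrite in plastids, rose from 7.80 ± 0.753 to 44.6 ± 10.4 (log2 2.42 ± 0.20, limma FDR 0.000324), and nitrate reductase from 3.32 ± 0.767 to 11.9 ± 5.71 (log2 1.63 ± 0.30, limma FDR 0.0118), with 2 of 3 genes of nitrate reduction rising (adjusted p = 0.578). Phosphate uptake genes rose in 7 and fell in 1 of 10 cases (adjusted p = 0.120). The gene that fell was described as Purple acid phosphatase 2, and so was a riser whose sum over isoforms did not pass. Members of these groups come from the authors' selection on these samples.

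Pectin-degrading polygalacturonases fell in 11 and rose in 1 of 13 cases (Fisher's exact test, adjusted p = 0.00940), from 0.0186 ± 0.0151% to 0.00123 ± 0.000159% of reads, with control 1 at 0.0355%, control 2 at 0.0141% and control 3 at 0.00632%. Protease inhibitors fell in 4 of 5 cases (adjusted p = 0.0699), with shares of reads of 0.381, 0.155 and 0.118% in control 1, 2 and 3 and 0.0531 ± 0.0177% in IPA. Glutathione S-transferases, which conjugate reactive compounds, fell in 5 of 8 cases and rose in none (adjusted p = 0.0350). Class III peroxidases fell in 16 and rose in 5 of 25 cases (adjusted p = 0.0130), while their summed share of reads was 0.0747 ± 0.00531% in control and 0.0759 ± 0.00709% in IPA (two-sided exact permutation p = 0.9). Transposon polyproteins fell in 13 and rose in 3 of 40 cases (adjusted p = 0.0130), with 24 not called. The planned organelle and transposon list, which shares members with this group, did not keep that direction with library totals (10 rose, 10 fell) or without IPA 1 (3 rose, 2 fell). Metacaspases (1 rose, 2 fell of 4, adjusted p = 0.628), TIFY repressors of jasmonate signalling (2 rose of 3, adjusted p = 0.578) and leucine-rich-repeat receptor-like kinases (7 rose, 7 fell of 18, adjusted p = 0.789) did not pass. Members of all these groups, too, came from the authors' selection on these samples. Heat shock 70 kDa protein 1 rose from 195 ± 75.3 to 795 ± 162 (log2 2.10 ± 0.31, limma FDR 0.00439), and DnaJ homolog subfamily B member 1 fell from 393 ± 91.2 to 79.9 ± 3.28 (log2 -2.27 ± 0.20, limma FDR 0.000389). The latter values lie close to those given above for Anthranilate phosphoribosyltransferase, so these descriptions may not mark separate changes, which was not tested.

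Transcripts with ribosomal RNA descriptions fell in 5 of 6 genes and plastid-encoded ones in 6 of 16. Their shares of reads were lower in every IPA library than in every control library, though the authors had selected these members as changed on these samples. Of 19 mitochondria-encoded genes 2 fell, and the share in IPA 2 (0.0569%) lay above that in control 3 (0.0471%). These classes were not fully separate: ycf68 of the plastid operon was in the ribosomal class, and cytochrome b came from the same Trinity gene. The deposited scaling factors are argued against only within a narrow range. The median log2 change of the 3 classes stayed at -1.49 or further from 0 under 4 other scalings (-1.77 here). Those scalings moved the median transcript by only -0.017 to 0.25 log2, which could not have brought the classes near 0. Larger scaling errors were not tested. More RNA without a poly(A) tail carried into the control libraries may also lower all 3 classes, and 2 of 3 had every IPA library below every control library in the median member (gaps of 0.96 and 0.07 log2, against -0.10 for the mitochondrial class). That carry-over and an effect of IPA on these transcripts cannot be told apart here, because the carry-over would follow the groups and no other measure of RNA quality was used.

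Nuclear photosystem genes were higher in the IPA libraries. Control 1, which lay furthest from the IPA libraries, was not the source of the calls: without it 30 of 30 genes still rose. The count was 25 without control 2, 30 without control 3, 29 without IPA 1, 22 without IPA 2 and 25 without IPA 3. The deposited scaling factors are argued against here too only within that narrow range. Under the 4 other scalings, with shifts of -0.017 to 0.25 log2 for the median transcript, the median log2 change closest to 0 was 1.75. Larger scaling errors were not tested. A response of these genes to IPA may remain as a hypothesis, found and tested on the same libraries, with culture conditions that went with the groups left untested.

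The control libraries were spread along the direction that separates IPA from control. A difference between control samples along the treatment axis may be involved: across transcripts, control 1 minus control 3 correlated at -0.26 with the IPA mean minus control 2, where transcripts are not independent replicates, and the other pairings gave 0.02 and -0.33. The trait was not particular to the controls: IPA 1 minus IPA 2 correlated at -0.29 with IPA 3 minus the control mean, and the other IPA pairings gave -0.08 and 0.14. Sampling noise of low-count transcripts is argued against, because the same correlation was -0.34 among 16094 transcripts with a mean normalised count of 10 or more. What set the control samples apart, such as harvest, culture state or RNA quality, stays open and untested.

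Over the 10 splits of the 6 libraries into 3 and 3, the real split was the 1 with as many calls, both for all transcripts (6587, highest other 0) and for those of at least 2-fold (3776, highest other 0), and 10 splits are too few for a share under 0.05. The 9 other splits gave 0 calls with limma and 0 with edgeR's quasi-likelihood test, and at most 4831 transcripts at an unadjusted limma p under 0.05 against 20892 for the real split.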
